A study of Drosophila melanogaster with 8 samples.

How the data were processed

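Polyadenylated RNA was measured by RNA sequencing in ovaries of Drosophila melanogaster that had been enriched for cells resembling germline stem cells (GSC-like cells). The samples fell into 2 groups of 4 replicates, a control and an overexpression of Stonewall (Stwl), a DNA-binding protein of the female germline. Per the labels' protocols, females were 4 to 5 days old, about 35 ovaries were dissected for each sample, RNA was extracted on columns and treated with DNase, and libraries were made with a TruSeq mRNA kit. The genetic tools used to enrich the cells and to drive Stwl are not given in the sources used here. The label of the treated group carries the suffix EY, and the 2 genes y and w were therefore fixed as markers of a P{EPgy2} insertion. The labels do not say whether replicates came from separate crosses, so p-values measure the spread between these samples only. Nor do they say whether both groups share a genetic background. A difference between strains therefore cannot be told apart from an effect of Stwl in any comparison here.

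The authors deposited TPM values (transcript abundances scaled to the same sum in every library) for 14094 genes in each of the 8 libraries. Per the submitters' processing notes, Salmon 1.10.1, DESeq2 1.37.4 and the genome build BDGP 6 were used, with no role or order given for them. The headers of these columns name a log2 TPM, but the deposited TPM values are linear, since each column sums to 1000000 within rounding, and they were used as linear values. TPM keeps no depth, so the depth of each library is unknown and no counting interval could be given. The authors also deposited a table of their own comparison for 11397 genes, in which the log2 fold change and its standard error are on the log2 scale and the p-values are raw and adjusted, per the file headers. That table further marks each gene as Up, Down or not changed, names other studies in which it was upregulated, and says whether a Stwl peak lies within 1 kb of the gene body. The conditions of the other studies and the origin of the peaks are not given in the file.

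Gene symbols came from the authors' table or, where it lacked a gene, from the reference annotation (Ensembl release 115). Of the 14094 genes, 14048 had a position in that annotation, which was used for coordinates, and 3 had no symbol in either source. For the main comparison, genes with a mean of at least 1 TPM over the 8 libraries were kept, which left 8898. Values were transformed to log2(TPM + 1), so a fold change understates the change of low genes. A linear model with the group as its only term was fitted with limma 3.58.1 in R 4.3.3, with an empirical Bayes variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values of single genes come from this limma fit unless the authors' deposited table is named. On simulated data for these 8898 genes with 200 of them changed, the fit recovered 67.2% of the genes changed by 0.5 log2, 88.1% of those changed by 1 and 97% of those changed by 2. Of all its calls, 6.15% were false. In 20 simulated sets with no change, 2 genes and 2 of 480 list tests passed. The simulated genes varied independently of each other, so this does not show how list tests behave on correlated genes.

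Before the data were examined, 25 gene lists, the rule for naming genes, the fit and its alternatives were fixed. The rule named stwl, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap and that had at least 5 TPM in the higher group. It added the 5 further genes in each direction with the smallest adjusted p, up to 4 called members of each list or else its 2 most abundant members, the genes bam, bgcn, nos, Dad and Sxl, and the neighbours of stwl. It took 87 genes in all. The 24 lists with at least 5 tested genes were tested as sets with camera and a preset correlation of 0.01, and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Single values were compared with 2-sided exact permutation tests, for which 4 against 4 samples allow no p below 0.0286. Marks of the authors' table were compared by Fisher's exact test and against 10000 random draws of tested genes matched on mean TPM in 20 bins.

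The alternatives were other pseudocounts, filters, scalings between libraries, variance priors and library weights, a replicate block, a fit without the 20 most abundant genes, each library left out in turn, and the authors' deposited test. DESeq2 and edgeR were not run here, because the values are not counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.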

Results

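RNA was measured in 8 ovary samples enriched for GSC-like cells, 4 controls and 4 with Stwl overexpression. The aim was to ask how more Stwl changes gene expression in such cells. Whether the groups share a genetic background is not given, so any change named below may also reflect strain. Between 8618 and 8941 genes had at least 1 TPM in a library. The 20 most abundant genes of each library took 20.9% to 26.5% of its TPM. The first principal component of the 8898 tested genes held 34% of the variance and separated the groups, with controls between -21.7 and -13.6 and overexpression libraries between 9.06 and 25.6. The second held 19.8% and spread libraries within groups. Overexpression replicates 1 to 4 lay at 27.4, 11.3, -8.68 and -15.7 on it, and controls 1 to 4 at 2.36, 3.93, -10.4 and -10.2. On the third, with 16.2%, control 3 stood apart at 28. No 2 libraries held identical values. Correlations of log2(TPM + 1) across genes were 0.971 to 0.987 within controls, 0.973 to 0.987 within overexpression libraries and 0.962 to 0.978 between the groups.

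The gene stwl itself (FBgn0003459, chromosome 3L, 14402930 to 14409939, minus strand) rose in all 4 overexpression libraries. Its abundance was 23.5 ± 1.31 TPM in controls and 57.9 ± 9.65 TPM with overexpression (SD, n = 4 each), a 2.38-fold change on the log2(TPM + 1) scale with a 95% confidence interval of 1.99 to 2.85. The log2 fold change was 1.25 with a standard error of 0.115 and an adjusted p of 0.000323 in limma. The groups did not overlap, and the 2-sided exact permutation p was 0.0286, the smallest that 4 against 4 samples allow. In the authors' deposited table the log2 fold change of stwl was 1.26 with a standard error of 0.0721. The marker gene y, which makes body pigment, went from 0.0255 ± 0.0264 to 2.5 ± 0.634 TPM (SD, n = 4 each, log2 fold change 1.75, adjusted p 0.000406 in limma). The eye colour gene w did not pass the test (log2 fold change -0.28, adjusted p 0.467 in limma). It was already at 23.4 ± 5.14 TPM in controls, against 19.1 ± 4.51 TPM with overexpression (SD, n = 4 each), so w tells little about the insertion. The annotated neighbour of stwl at its 3' end, CG3868 (chromosome 3L, 14400769 to 14402725), did not pass the test either (log2 fold change 0.06, standard error 0.63), but this value rests on control 3. CG3868 was at 9.66 TPM in control 3, at 0.147 to 0.624 TPM in the other controls and at 0.989 to 1.75 TPM in the overexpression libraries, and without control 3 it fell below the minimum abundance and was not tested. The neighbour on the other side, lncRNA:CR45233, was not analysed here.

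With Stwl overexpression, 552 of the 8898 tested genes were higher and 194 were lower at an adjusted p of 0.05 in limma. Of these, 79 rose and 27 fell at least 2-fold. The 2-fold counts were 133 and 49 with a pseudocount of 0.1, and 54 and 16 with a minimum mean of 5 TPM. They were 212 and 103 in the authors' deposited table. With library weights they were 119 and 68, among 2293 higher and 804 lower genes. Most changes were modest, with a median absolute log2 fold change of 0.597 among called genes. The groups did not overlap for 536 of the higher and 193 of the lower genes, and for 16% of all tested genes, against 2.86% by chance. Higher genes made up 74% of the calls. With median-of-ratios scaling, quantile normalization and without the 20 most abundant genes, calls grew in both directions, to 806, 663 and 657 higher and 626, 715 and 379 lower genes, and the higher share was 56.3%, 48.1% and 63.4%. It was 55.5% in the authors' deposited table, which comes from another test. Leaving out overexpression replicate 1 raised the higher genes to 988, while leaving out control 4, overexpression 2 or overexpression 3 lowered them to 354, 340 and 336. The lower genes came to 106, 99, 103 and 105 without control 1, control 3, control 4 or overexpression 2.

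Of the 75 genes named by the rule that passed the test, 51 passed under every other setting fixed beforehand in which they were tested and 24 lost the call under at least 1, of which 21 did so when 1 library was left out. The 24 were Cp15, Cp16, Cp7Fa, Cp19, Rbp9, mei-W68, grk, bcd, squ, mael, insv, Hk, gbb, dpp, Timp, Obp99a, DptB, Dro, RnrS, Nop56, RpL23A, RpL19, ATPsynbeta and Rpt6R. Of the 51, 7 fell below the minimum abundance under at least 1 setting and were not tested there, mthl4, Cyp6a17, CG12519, CG5568, slo, eater and y. Across these settings the highest adjusted p of the 24 lay between 0.055 for RnrS and 0.178 for Cp19.

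Among the genes with the largest rises was Fuca, an alpha-L-fucosidase, which went from 3.29 ± 0.428 to 32.1 ± 5.21 TPM (SD, n = 4 each; log2 fold change 2.94 with a standard error of 0.13). CG12592 rose by 2.75, the methuselah-like receptor gene mthl4 by 2.28, CG13332 by 2.02 and CG12814 by 1.91 on the log2 scale. The histone gene copy His2B:CG33882 was listed at 0 in all 4 controls and at 318, 267, 136 and 398 TPM in overexpression replicates 1 to 4. Histone genes are near-identical repeats, so the assignment of reads to this copy is uncertain. The chorion genes Cp15, Cp18, Cp16 and Cp7Fa, which encode eggshell proteins, completed the 10 largest rises, with log2 fold changes of 5.17, 4.70, 4.66 and 2.86. The smallest adjusted p-values among further higher genes belonged to the ribosomal protein paralogue RpL37b (47.6 ± 4.3 against 121 ± 6.98 TPM, SD, n = 4 each), the cytochrome P450 gene Cyp4p2, CG42857, CG13299 and pst, with log2 fold changes of 1.33, 1.40, 1.11, 0.96 and 1.77.

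The largest falls were in 2 overlapping genes of chromosome 3R. Unc-115b (9687060 to 9692775), related to actin-binding proteins, fell from 40.4 ± 2.58 to 0.263 ± 0.436 TPM (SD, n = 4 each), and p24-2 (9687402 to 9692794), a cargo receptor family gene, from 24.3 ± 1.01 TPM to a listed value of 0 in every overexpression library. Because the 2 genes overlap, their reads cannot be fully told apart. The cytochrome P450 genes Cyp9b2 and Cyp6a17 fell with log2 fold changes of -2.90 and -2.68, and CG12519, CG18278, CG18586 and CG5568 with values of -2.19, -2.05, -1.88 and -1.78. Arc1, whose protein forms virus-like capsids, fell from 157 ± 35.1 to 58 ± 13.8 TPM, and RpS19b, a ribosomal protein paralogue, from 375 ± 23.3 to 151 ± 14.1 TPM (SD, n = 4 each). The smallest adjusted p-values among further lower genes belonged to Yeti, the transcription factor gene retn, the lipid droplet protein gene sturkopf, CG14985 and CG12608, with log2 fold changes of -0.57, -0.92, -0.55, -0.87 and -0.57.

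Among genes of stem cell maintenance and BMP response, 1 of 22 changed. Dad, an inhibitory Smad gene induced by BMP signalling, rose from 7.61 ± 0.914 to 12.4 ± 1.92 TPM (SD, n = 4 each; log2 fold change 0.63, adjusted p 0.013 in limma). The translational repressor gene nos was at 105 ± 7.24 and 103 ± 16.7 TPM and did not pass the test (adjusted p 0.917 in limma). Of 16 cystoblast differentiation genes, 2 rose and 1 fell. The gene bgcn, whose product acts with Bam to start differentiation, fell from 55 ± 3 to 30.8 ± 5.85 TPM (log2 fold change -0.83, adjusted p 0.00429 in limma), whereas bam itself was at 7.23 ± 0.68 and 7.13 ± 0.855 TPM (SD, n = 4 each). The gene tut, which encodes a partner of Bam and Bgcn in the male germline, rose by 0.64, and the RNA-binding protein gene Rbp9 by 0.46 on the log2 scale. Sxl had a log2 fold change of -0.18 and did not pass here, but it passed in the authors' deposited table with an adjusted p of 0.0248. Neither list passed as a set (camera adjusted p 0.368 and 0.0734), but the differentiation list passed with median-of-ratios scaling, with no filter on low values and without overexpression replicate 4 (adjusted p 0.0333, 0.0371 and 0.0259). With an estimated correlation, the camera adjusted p of each list was 0.915.

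**Figure D1:**
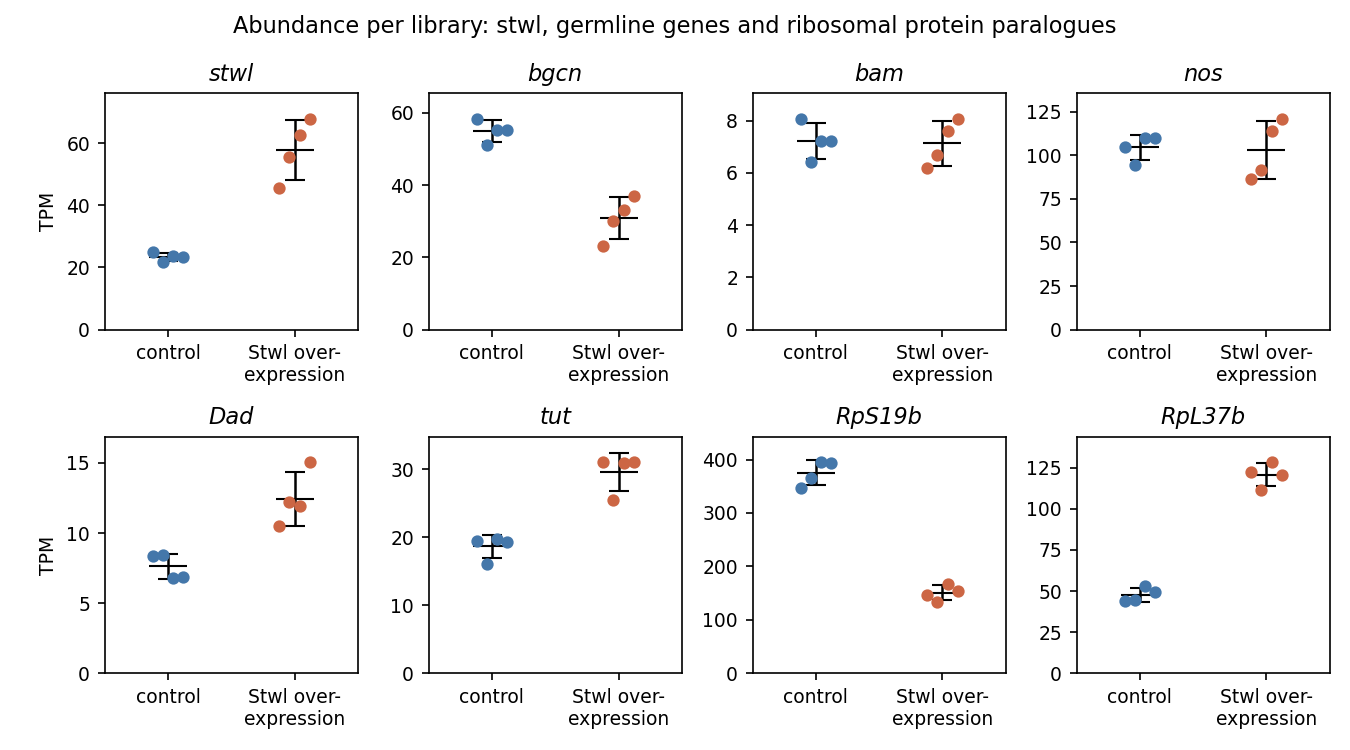
Abundance in TPM on the vertical axes of stwl, 5 germline genes and 2 ribosomal protein paralogues in the 4 control (blue) and 4 Stwl overexpression (orange) libraries. Points are libraries and black bars give the mean and SD; stwl went from 23.5 to 57.9 TPM and bgcn from 55 to 30.8 TPM, while bam stayed at 7.23 and 7.13 TPM.

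Among meiotic, piRNA pathway and maternal genes, 9 fell and 1 rose. Of 25 synaptonemal complex and recombination genes, 3 fell: the crossover gene hdm, the cohesion gene solo and mei-W68, which encodes the enzyme that makes meiotic breaks, with log2 fold changes of -0.62, -0.50 and -0.52. Of 30 piRNA pathway genes, moon, squ and mael fell, with values of -0.61, -0.37 and -0.36, and 7 were lower adjusted over the list alone. Of 24 oocyte fate and maternal genes, plu, trk and bcd fell, with values of -0.87, -0.93 and -0.62, and grk rose by 0.38, while 6 were lower adjusted over the list alone. These 3 lists passed as sets with a preset correlation (camera adjusted p 0.000213, 0.000335 and 0.0466, medians -0.16, -0.10 and -0.02), but each had an adjusted p of 0.914 with an estimated correlation. For the list means of the libraries, the exact permutation p was 0.0571, 0.229 and 0.543. Without overexpression replicate 1 the synaptonemal and piRNA medians were -0.08 and -0.03. From overexpression 1 to 4 the mean log2(TPM + 1) climbed stepwise, from 4.295 to 4.593 for the synaptonemal and from 5.44 to 5.82 for the piRNA list. Abundance of stwl climbed in the same order, from 45.5 to 67.8 TPM. Overexpression 4 thus lay within the control range of the synaptonemal list (4.568 to 4.697), and its piRNA mean of 5.82 compares with 5.79 ± 0.042 in controls (SD, n = 4). The oocyte list lost its preset call with median-of-ratios scaling (adjusted p 0.0774) and without control 1, control 4, overexpression 2, overexpression 3 or overexpression 4 (adjusted p 0.0707, 0.0596, 0.167, 0.0852 and 0.0811). In overexpression replicate 1 its mean log2(TPM + 1) stood at 4.41 against 3.93 to 4.22 in the other overexpression libraries.

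Cell cycle and DNA replication genes had a median log2 fold change of -0.10, and 25 of 32 were below 0, yet 1 passed alone: RnrS, a ribonucleotide reductase subunit, with a log2 fold change of -0.22. Without overexpression replicate 1 the median was -0.04, and the mean log2(TPM + 1) of overexpression 4 was 6.11, against 6.03 to 6.08 in controls. Ribosome biogenesis genes had a median of -0.08, and 1 of 23 fell, Nop56, with a value of -0.21, or 0 adjusted over the list alone. Both lists passed with the preset correlation (camera adjusted p 0.000413 and 0.000335), but their adjusted p was 0.914 and 0.695 with an estimated correlation. Among 85 cytosolic ribosomal proteins, 7 fell and 1 rose, or 8 and 2 adjusted over the list alone, and the list's median was -0.02 (camera adjusted p 0.0233, and adjusted p 0.915 with an estimated correlation). Its direction turned with quantile normalization, where the median was 0.01, and its preset call ended without control 2, control 3, control 4 or overexpression 4 (adjusted p 0.0682, 0.0581, 0.0797 and 0.999). Besides RpS19b and RpL37b, whose log2 fold changes were -1.31 and 1.33, RpL23A and RpL19 fell, with values of -0.26 and -0.24, but did not pass with median-of-ratios scaling.

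Of 21 genes of the muscle that sheathes the ovary, 16 rose, or 17 adjusted over the list alone. All 21 had a positive log2 fold change, with a median of 0.64. The light chain gene Mlc2 went from 207 ± 22.2 to 364 ± 32.9 TPM, TpnC73F from 158 ± 15.1 to 274 ± 29.5 TPM, Mp20 from 589 ± 61.8 to 918 ± 78.4 TPM and Prm from 70.6 ± 8.57 to 117 ± 11.2 TPM (SD, n = 4 each). The list passed with the preset correlation (camera adjusted p 2.46e-14) and with fry (adjusted p 0.0391), and its adjusted p was 0.746 with an estimated correlation. Of 20 hemocyte and basement membrane genes, 7 rose, or 8 adjusted over the list alone, with a median of 0.31. They included the hemocyte receptor genes Sr-CI and eater, the prophenoloxidase gene PPO1 and SPARC, which rose by 1.05, 0.93, 0.96 and 0.47 on the log2 scale (camera adjusted p 0.000213 for the list, and adjusted p 0.914 with an estimated correlation).

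Genes of the niche, escort cells and early follicle cells had a median of 0.25, with 3 of 28 higher, or 5 adjusted over the list alone. The BMP ligand genes gbb and dpp rose by 0.32 and 0.68, and the protease inhibitor gene Timp by 0.33 (camera adjusted p 0.000927 for the list, and adjusted p 0.914 with an estimated correlation). The groups overlapped in the mean log2(TPM + 1) of this list, with an exact permutation p of 0.114. Overexpression 1 was at 4.029, within the control range of 3.976 to 4.105. Of 26 yolk, vitelline membrane and chorion genes, 9 rose, 8 chorion genes and pip, a sulfotransferase gene of follicle cells, which was named after its value was seen. The 9 chorion genes had a mean log2(TPM + 1) of 4.17 ± 1.35 in controls and 7.79 ± 0.974 with overexpression (SD, n = 4 each), and 10 genes taken as yolk and vitelline membrane genes 11.8 ± 0.273 and 11.8 ± 0.337. These 10 were picked by name (Yp or Vm) among all tested genes, so they need not all belong to the list. Chorion levels varied widely between libraries: Cp15 was at 52.8 ± 49.2 and 1761 ± 1807 TPM (SD, n = 4 each), and Cp19 did not pass in the authors' deposited table (adjusted p 0.178). The list's call (camera adjusted p 0.0192, and adjusted p 0.914 with an estimated correlation) ended without overexpression replicate 1 or control 4, where the adjusted p was 0.685 and 0.0797.

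**Figure D2:**
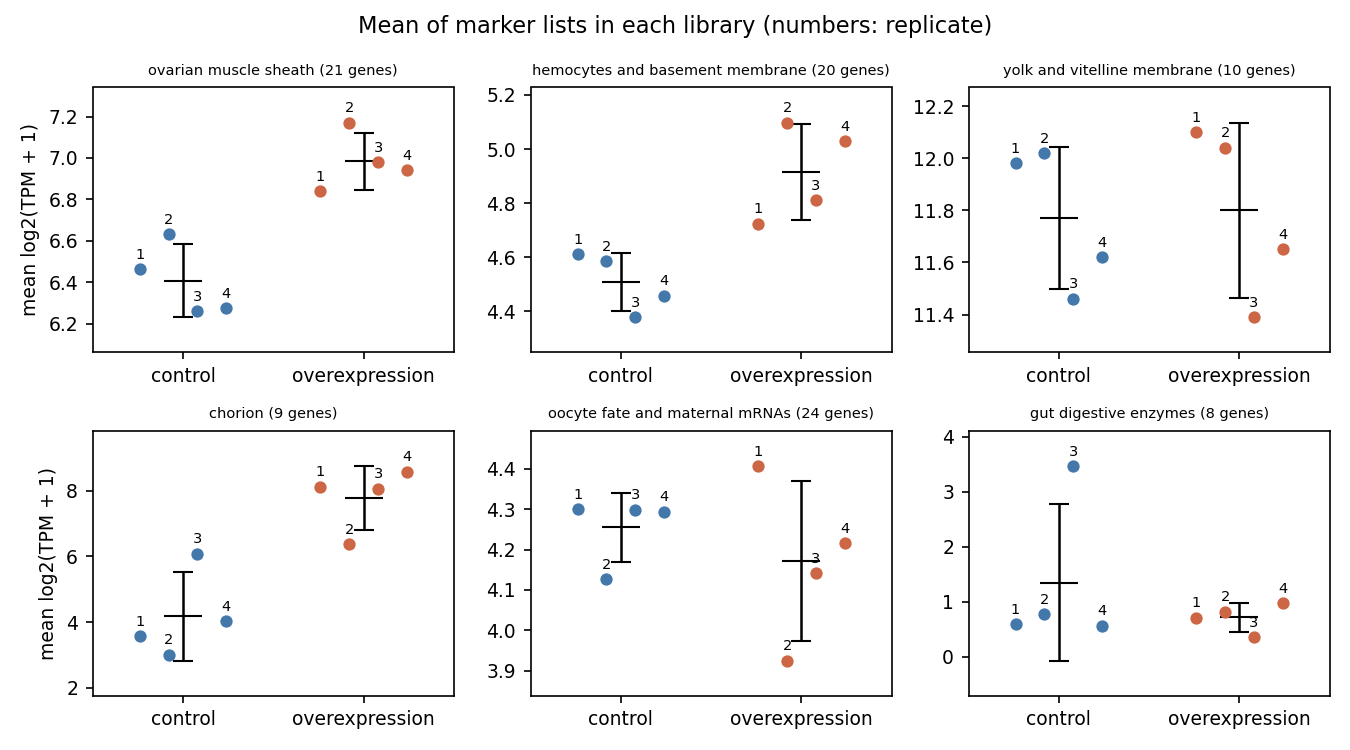
Mean log2(TPM + 1) of 6 marker lists on the vertical axes in each control (blue) and overexpression (orange) library, with replicate numbers beside the points and black bars for the mean and SD. Muscle sheath means were 6.41 in controls and 6.98 with overexpression; control 3 stood alone for gut digestive enzymes at 3.47, and overexpression replicate 1 was highest for oocyte genes at 4.41.

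The other lists did not pass as sets in the comparison of all 8 libraries, and some passed under other settings. Of 14 insulator protein genes, 2 rose, Elba3 by 1.14 and insv by 0.35 on the log2 scale, or 3 adjusted over the list alone. The insulator list had a camera adjusted p of 0.0557, and of 0.914 with an estimated correlation. It passed with median-of-ratios scaling, quantile normalization, library weights, a minimum mean of 5 TPM, without the 20 most abundant genes, and without control 1, overexpression 1 or overexpression 2 (adjusted p 0.0321, 0.0231, 0.0395, 0.0325, 0.0461, 0.0428, 0.0371 and 0.0464). None of the 23 heterochromatin and nuclear periphery genes changed in limma, and HP4, which encodes a partner of heterochromatin protein HP1, had a log2 fold change of 0.09 and passed only with library weights (adjusted p 0.0405). Phf7, which promotes male fate in the germline, rose by 0.48 as 1 of 15 testis genes, of which 1 other was lower adjusted over the list alone. The potassium channel genes slo and Hk rose by 0.66 and 0.58 among 11 neuronal genes, and the cell death genes skl and egr by 0.77 and 0.48 among 23 genes of DNA damage response and apoptosis. For the neuronal and apoptosis lists the medians (-0.07 and -0.03) were below 0 and the means and tests above it, and for the immune list the test pointed down with a median of 0.07.

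Of 25 immune effectors, the antimicrobial peptide gene Dro rose from 80.7 ± 15.1 to 185 ± 76.1 TPM (SD, n = 4 each) and DptB fell, with a log2 fold change of -0.71. Of 12 fat body genes, Obp99a fell, with a value of -0.80. No member passed among 16 heat shock genes, where Hsp83 and Hsp27 had log2 fold changes of -0.13 and -0.42, or among 16 ecdysone genes, where Eip75B and Cyp18a1 had values of 0.05 and 0.01. Hsp27 did pass with median-of-ratios scaling, quantile normalization, without the 20 most abundant genes and without overexpression replicate 3 (adjusted p 0.0135, 0.0118, 0.0258 and 0.00931), and its adjusted p in the authors' deposited table was 7.93e-05. No member passed among 8 gut digestive enzymes, whose mean log2(TPM + 1) was 3.47 in control 3 and at most 0.973 in the other libraries. Of 61 oxidative phosphorylation genes, ATPsynepsilonL rose by 0.82 and ATPsynbeta fell, with a value of -0.20, and of 37 proteasome genes Rpt6R rose by 0.37. Camera adjusted p-values of the lists in these last paragraphs other than insulators were between 0.113 and 0.973. The proteasome list passed with median-of-ratios scaling, quantile normalization, library weights and without the 20 most abundant genes (adjusted p 0.035, 0.00202, 0.0383 and 0.0241), and the gut list with no filter on low values, library weights and without control 1 (adjusted p 0.036, 0.00885 and 0.023). The heat shock list passed without overexpression 3 and the oxidative phosphorylation list without overexpression 4 (adjusted p 0.00148 and 0.0442). With an estimated correlation, the proteasome, gut, heat shock and oxidative phosphorylation lists each had a camera adjusted p of 0.915.

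**Figure D3:**
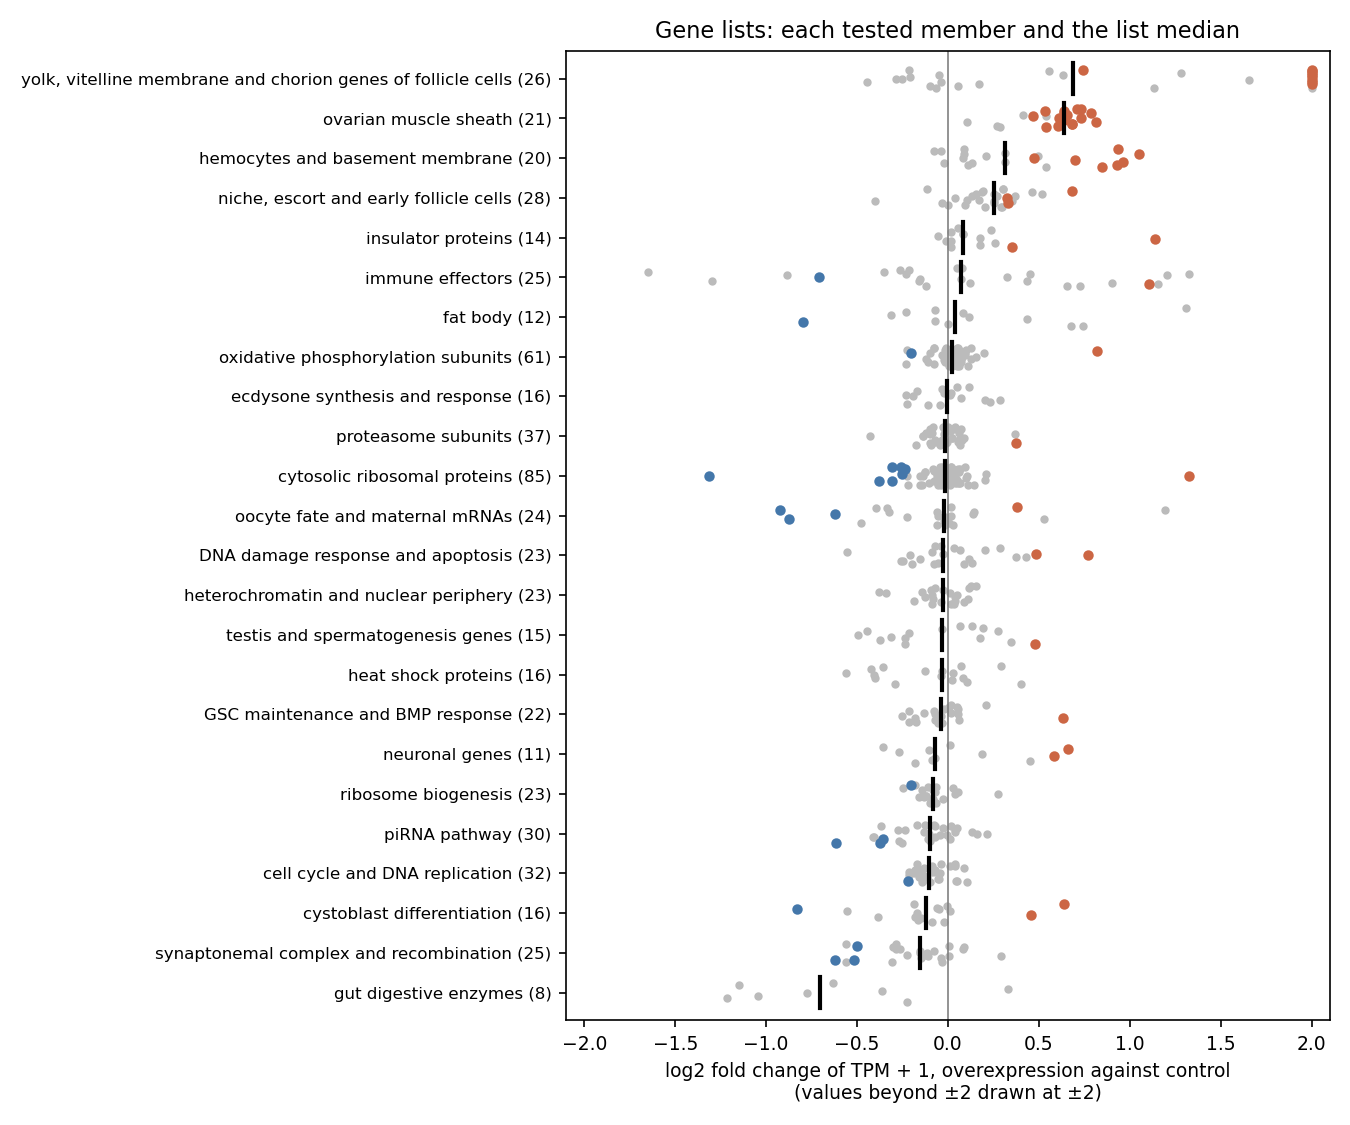
Log2 fold change of TPM + 1 (horizontal axis) of every tested member of the 24 lists tested as sets, with the number tested in parentheses. Orange and blue points are genes higher and lower at an adjusted p of 0.05, grey points did not pass, and black bars are list medians; the 21 muscle sheath genes all lie above 0, around a median of 0.64.

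In the authors' deposited table, 1113 genes were higher and 893 lower at an adjusted p of 0.05, and 394 were marked Up and 154 Down. Of the genes called here, 538 of the 552 higher and 188 of the 194 lower genes passed there in the same direction, and none passed in the opposite one. That table also marks genes upregulated in studies by Kotb and by Zinshteyn and their colleagues. Of the 552 higher genes, 394 (71.4%) carried the mark of at least 1 of these studies, whose conditions the table does not give, and 258 carried both. The mark was on 24.4% of the 8888 tested genes in the table and on 21.5% of those not called in either direction. Fisher's exact test, which set called genes against all other tested genes, gave an adjusted p of 5.29e-128. Of the 194 lower genes, 27 (13.9%) carried it (adjusted p 0.00054 in the same test, whose other genes include the marked higher ones). Draws matched on mean TPM gave 24.1% to 31.2% for the higher and 21.1% to 33.5% for the lower genes.

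A Stwl peak within 1 kb was marked for 74.8% of the higher and 65.5% of the lower genes, against 79.5% of all tested genes and 80.2% of those not called. Fisher's exact test against the other tested genes gave adjusted p-values of 0.00546 and 1.05e-05. Matched draws gave 74.6% to 81.2% and 72.2% to 83.5%, so the share of the higher genes lay within the matched range and that of the lower genes below it. Muscle sheath genes moved with the groups as well: the mean log2(TPM + 1) of their list was 6.41 ± 0.176 in controls and 6.98 ± 0.138 with overexpression (SD, n = 4 each).

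**Figure D4:**
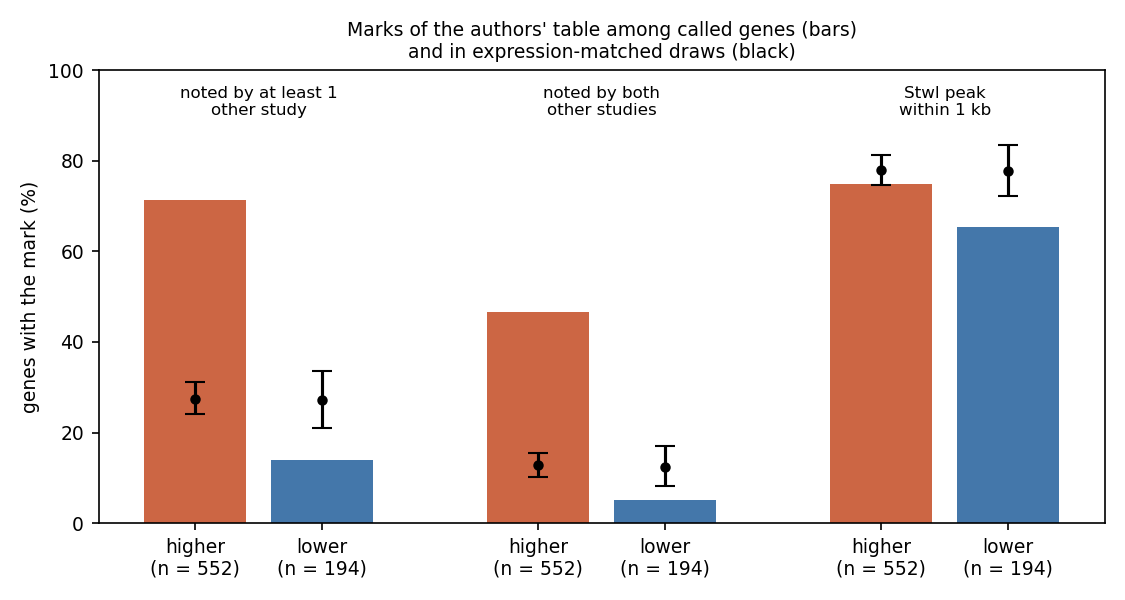
Percent of called higher (orange, n = 552) and lower (blue, n = 194) genes that carry each mark of the authors' deposited table, with black points and bars for the median and central 95% of 10000 draws matched on mean TPM. Higher genes carried a mark of another study in 71.4% of cases, against 24.1% to 31.2% in matched draws.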

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

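Each value here was the highest or lowest of a group of 4 libraries by a gap to its nearest neighbour that, relative to the range of the group, exceeded Dixon's critical value. Of 222 groups of named genes and list means, 14 were picked out in this way, where chance gives about 11.1, so single cases carry little weight.

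Control 3 held 45.7 TPM of Jon99Fi, which was listed at 0 in the other controls, and 29.9 TPM of Jon65Ai, against at most 0.22. Its mean log2(TPM + 1) over the gut digestive enzyme list was 3.47, against 0.563 to 0.774 in the other controls. It also held 9.66 TPM of CG3868, the neighbour of stwl, and 6.76 TPM of the cell death gene skl. Control 2 was lowest for tut at 16.1 TPM, for mael at 108 TPM, for the oocyte and maternal list at 4.13 and for the cell cycle list at 6.03. Control 1 was lowest for CG12592 at 1.69 TPM and for insv at 13.8 TPM. Overexpression replicate 1 was lowest in its group for CG12592 at 19.3 TPM and for CG18278 at 0.438 TPM, and overexpression replicate 2 was lowest for tut at 25.5 TPM.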

How the results depend on the processing

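stwl kept its direction and call under every setting fixed beforehand, with log2 fold changes of at least 1.17, and of 1.17 to 1.36 without single libraries. The fits with the muscle sheath mean or a split by replicate number as a term, and the fit without control 3 and overexpression 1, were chosen after seeing the data. Causes of the changes below were not tested unless stated.

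Higher genes numbered 2293 with library weights, 1113 in the authors' test and 853 with replicates 1 and 2 against 3 and 4 as a term. Lower genes numbered 626 with median-of-ratios scaling, 715 with quantile normalization, 804 with weights, 379 without the 20 most abundant genes, 398 with the split as a term and 893 in the authors' test. Genes past a 2-fold change numbered 133 higher and 49 lower with a pseudocount of 0.1, which shrinks low genes less, 119 and 68 with weights, and 212 and 103 in the authors' test. With a minimum mean of 5 TPM, which tests fewer genes, 16 were lower. Without 1 library, 336 to 988 genes were higher and 99 to 248 lower. Without both control 3 and overexpression 1, 752 were higher and 147 lower.

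With the muscle sheath mean as a term, 13 genes were higher and 5 lower, all of them past a 2-fold change, and stwl had a log2 fold change of 1.22 (adjusted p 0.276), with a standard error of 0.284 in place of 0.115. That mean correlated with the group at 0.903, which inflates the error, while fold changes had a median ratio of 0.849 to their former size, so lost calls do not show lost effects. Under it Dro turned to -0.29, the oocyte list to 0.13, the hemocyte list to -0.00242 and the ribosomal protein list to 0.0505. The medians of the niche, chorion and muscle lists were 0.23, 0.75 and 0.0523, the last by construction.

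Of 24 lists, 10 passed, 4 with the muscle mean as a term and 0 with an estimated correlation. That last setting leaves the medians as they were and ended the calls of the muscle (0.64), chorion (0.69), hemocyte (0.31), niche (0.25), synaptonemal (-0.16), piRNA (-0.10), cell cycle (-0.10), ribosome biogenesis (-0.083), oocyte (-0.0194) and ribosomal protein (-0.0162) lists. At an unadjusted p under 0.05, 1 list passed there. The insulator list passed with the split as a term (adjusted p 0.0471). The oocyte call also ended with median-of-ratios scaling (-0.0485), quantile normalization (-0.0706) and without the 20 most abundant genes (-0.037), and the ribosomal protein call with median-of-ratios scaling (-0.0471), turning to 0.0102 with quantile normalization. The chorion list test turned down with weights, with a median of 0.31, and was lost with the split as a term (0.69) and without both libraries (0.72). Without single libraries the oocyte list ranged from -0.0825 to 0.0249, the chorion list from 0.51 to 0.87 and the ribosomal protein list from -0.0319 to 0.00623.

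Replicate numbers did not pair the samples. Deviations of same-numbered libraries correlated at 0.13, -0.017, -0.13 and 0.14, and 3 of 8 libraries correlated best with their own number. With a replicate block, 202 genes were lower, 74% of the calls were higher, and 481 of the 552 higher and 152 of the 194 lower genes kept their calls, and Hsp27 passed (adjusted p 0.0252). Depth is unknown from TPM. DESeq2 and edgeR were not run, because the values are not counts.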

Other observations

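The genes and gene families in this paragraph and the next, the muscle sheath tests, the definition of genes switched on or off and the test on overlapping genes were chosen after the results were seen. Some ribosomal protein genes changed, while 77 of the 85 in the list did not pass; RpL22-like is not in that list. RpS5b fell from 1342 ± 84.3 to 1084 ± 49.5 TPM and RpL22 from 1545 ± 37.2 to 1299 ± 71.7 TPM, while RpL22-like rose from 75.8 ± 12.6 to 152 ± 13.6 TPM (SD, n = 4 each; limma adjusted p 0.0088, 0.00994 and 0.00111). RpS5a, RpS19a and RpL37a did not pass, with log2 fold changes of -0.05, 0.04 and -0.05, and differences between paralogues were not tested. RpL22 lost its call with median-of-ratios scaling (adjusted p 0.0529). BigH1, an embryonic and germline linker histone, fell from 60.4 ± 2.27 to 37.8 ± 4.48 TPM.

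Among cytochrome P450 genes, 11 of 53 rose and 4 fell (28.3% against 8.26% of other genes), with Cyp4p1 higher by 1.21 and Cyp305a1 by 0.61 on the log2 scale. In all, 17 patterns of gene names were looked at, several of them because called genes carried them, so the counts describe these families and no enrichment is claimed. Of 16 UDP-glycosyltransferases 5 rose and 1 fell, of 23 tetraspanins 6 rose, of 27 glutathione S-transferases 4 rose and 1 fell, and of 31 histone genes 6 rose. Of the 4 tested betaNACtes genes, named for their testis expression, 3 rose, among them betaNACtes3 from 3 ± 0.357 to 14.1 ± 2.41 TPM and betaNACtes1 from 0.493 ± 0.15 to 2.17 ± 0.59 TPM. Of 5 Skp genes 3 rose, with SkpE going from 19.4 ± 3.16 to 57.3 ± 7.12 TPM. Of 8 integrin adhesion genes 0 passed, but 2 were higher with median-of-ratios scaling and 1 with quantile normalization. Overexpression replicate 1 alone held much RNA of the oocyte genes osk and pgc, at 25.9 and 15.9 TPM, against at most 1.52 and 1.28 TPM in the other libraries.

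The real split gave 746 genes past the threshold and 106 past a 2-fold change. Of the 35 splits of the 8 libraries, 1 gave as many genes in each case, the real one, and the highest of the others gave 235 and 14. No share below 1 of 35 is possible here, so chance is argued against but not excluded. The split with 235 genes parted replicates 1 and 2 of both groups from replicates 3 and 4, which points to a structure of the samples that the labels do not give. With that split as a term, all 552 higher and 194 lower genes kept their calls.

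Of 21 muscle sheath genes 16 rose and of 20 hemocyte and basement membrane genes 7 rose, with set tests at an adjusted p of 0.746 and 0.914 with an estimated correlation. More muscle sheath with attached hemocytes in the dissected ovaries may account for it but cannot be told apart: the 24 muscle and hemocyte-restricted genes with at least 5 TPM had positive changes, which restates values already seen and decides nothing. A lower share of germline cells was taken to raise all other cell types alike, and it cannot be told apart here. The muscle mean rose by 0.55 log2 more than the yolk and vitelline membrane genes picked by name. This was above the SD of that difference in controls (0.131) and with overexpression (0.353). The groups did not overlap within replicates 1 and 2 (0.388) or within 3 and 4 (0.711), but they overlapped over all 8 libraries. The exact permutation p was 0.0571, which missed the bound of 0.05 first set for this test, and 0.0556 within these replicates, the smallest they allow. Muscle rose by 0.361 more than niche and escort genes (SD 0.228 and 0.179, exact permutation p 0.0571). Sets of other cell types rose unequally, by 0.214 (niche and escort), 3.62 (chorion) and 0.029 (yolk and vitelline membrane). The yolk genes therefore cannot stand for all other cell types. An effect of Stwl itself on the muscle and hemocyte genes would give the same values and was not tested.

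Higher genes overlapped with genes upregulated in the other studies. Expression level is argued against as its cause, since 71.4% carried the mark and matched draws reached 31.2%. RNA of muscle sheath and hemocytes could contribute: outside the muscle list, the 378 marked higher genes had a median within-group correlation of 0.38 with the muscle mean, against -0.11 for higher genes without a mark, and 0.42 with the muscle genes kept in. That value lies between the bounds of 0.2 and 0.5 set beforehand, so this explanation stays open, as does an effect of Stwl, which was not tested.

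The expression of 14 called genes was nearly switched on or off, with a mean under 0.5 TPM in one group and at least 2 TPM in the other, 7 in each direction. Variants carried on the third chromosome with stwl are argued against as the whole cause, since 42.9% lay on 3L or 3R by annotated position, against 43.1% of other tested genes. The gene y was counted on X in this way, although it was fixed as a marker of the insertion. With 14 genes, these shares cannot tell whether such variants account for some of them. Differing chromosome segments between strains cannot be told apart: 4 genes lay within 100 kb of another (permutation p = 0.011 over 10000 random draws), which met the bound set beforehand for this explanation, but a test added after that result, with overlapping genes taken as 1, gave a permutation p of 0.18. The 4 genes form the pairs p24-2 with Unc-115b and CR32011 with CR32010. The relatives eca and Unc-115a, beside p24-2 and Unc-115b, were at 193 ± 9.9 and 30.8 ± 1.14 TPM in controls and 186 ± 12.3 and 29.7 ± 3.86 TPM with overexpression, so their levels give no sign of reads moved to them, and an effect of Stwl was not tested.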
